A study of Mus musculus with 36 samples.

How the data were processed

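RNA of mouse T cells was measured on Illumina bead arrays, 36 arrays in 9 groups of 4 (3 genotypes at 0, 1 and 4 h of stimulation). Groups and replicate numbers were taken from the sample labels. Per the labels, RNA was made into biotin-labelled cRNA with the Ambion MessageAmp kit and the arrays were read with GenomeStudio 2011.1. The signal intensities are, per the file headers, non-normalized probe signals on a linear scale as deposited, with no background subtraction. The detection p-value of each probe on each array was computed by the authors' software against negative control beads and deposited beside the signal. The authors also deposited a processed table of intensities, which holds negative values and has a 75th percentile of 42.6 on every array, with medians from 3.73 to 3.81. This reads as background-subtracted intensities scaled across arrays, by a method that is not stated. Within each array it ranks the probes as the raw signals do (Spearman 1). No column of per-sample values was left out.

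The raw signals were background-corrected by the normexp model, with the background estimated from the detection p-values, quantile-normalized and put on the log2 scale after an offset of 16 (neqc in limma 3.58.1, R 4.3.3, statmod 1.5.0). Of 25697 probes 23978 carry 1 gene symbol and 1719 none. A probe was kept when its detection p-value was under 0.01 on at least 4 arrays, which left 10961 probes, 10314 of them with a symbol and 647 without. For 1985 genes with more than 1 such probe the brightest was used, so that 7585 genes were tested and 9008 symbols on the array were not. Detected probes per array averaged 8903, 9680, 8962 and 8219 over the arrays of replicates 1 to 4. The arrays of 1 group correlated at 0.934 to 0.989. Genes whose signals stay near background are not tested, and small changes of dim genes are compressed. A linear model with 1 mean per group was fitted to all arrays (27 residual degrees of freedom), with moderated variances. The 21 comparisons were 6 of stimulated against resting cells, 9 between genotypes at 1 time and 6 differences of responses. A gene passed at a Benjamini-Hochberg adjusted p of 0.05 within its comparison. Where n is small the printed p comes from limma, which pools variances over genes, or from an exact permutation of 4 against 4 arrays.

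Named genes are the 15 largest rises and 15 largest falls per comparison among genes past the threshold whose 4 and 4 values do not overlap (10 and 10 for the differences of responses), with Malt1 and members of the gene lists. This rule, the comparisons, the lists and all alternatives but 3 were chosen before the data were examined. The 28 gene lists, written by hand, are NF-kB targets, AP-1 and immediate early genes, NFAT and calcium response, cytokines and chemokines, activation surface markers, regulatory T cell markers, effector and memory genes, naive and quiescence genes, Regnase-1 and Roquin targets, MALT1 complex and substrates, interferon-stimulated genes, ribosome biogenesis, glycolysis, amino acid and one-carbon metabolism, cholesterol synthesis, cell cycle, apoptosis and survival, heat shock, T cell identity, and markers of CD8, CD4, B, plasma, myeloid, NK, erythroid and gamma-delta cells, with housekeeping genes. Each list was tested against all other genes by camera (limma) with a preset correlation of 0.01 between genes, 588 tests adjusted within each comparison, and again with an estimated correlation and by fry. Lists overlap, so their calls are not separate evidence. The Regnase-1 and Roquin list shares Rel, Tnf, Nfkbid, Nfkbiz, Zc3h12a, Irf4 and Ier3 with the NF-kB list, and Egr1 and Myc with the immediate early list. The NFAT list shares Il4, Il3 and Csf2, among others, with the cytokine list. A list score is the mean log2 signal of its measured members on an array.

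The size of a response was measured over genes with a mean change of at least 1 (log2) over the 3 genotypes. Each stimulated array was set against the mean of its genotype at 0 h. The overlap of PM and KO was compared with lists drawn independently. The correlation of their changes was compared with simulated data in which neither differs from het but the het arrays are shared. Chromosomes of genes were read from the gene table of assembly GRCm38.p6.

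The replicate numbers were checked as pairs by correlating group-centred arrays. Arrays of the same number correlated with a median r of 0.405 (-0.0718 to 0.827), those of different numbers at -0.132, and every pair exceeded 0.1 in 10 of 15 comparisons. The test was tried on simulated data built on PM against het at 4 h. Of the genes changed 1.5-fold 26 of 67 were found (38.8%), of those changed 2-fold 59 of 67 (88.1%) and of those changed 4-fold 65 of 66 (98.5%), with 11 calls among unchanged genes and 0 when nothing was changed. A list of 25 genes moved 1.5-fold was called, and 0 of 27 unmoved lists were. Genes and arrays were drawn independently there, so neither trial shows how often false calls arise among correlated genes or paired arrays. On the real arrays the estimated correlation between genes was 0.292 in the interferon list and 0.563 in the B cell list.

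Alternatives were the authors' table, no background correction, scaling to a common median, no filter or a stricter one (12 arrays), the mean of the probes of a gene, every probe on its own, the replicate number as a block or as a random effect, only the arrays of the groups compared, array weights, moderated variances with a trend and robust, and each array left out in turn. Replicates 1 to 3 alone were added after the data were seen, since the arrays of replicate 4 were dimmer, and so were the fits without 1 array for the percent of response genes that go against the smaller KO response and the share counted over response differences. Il2 is not analysed here. Probes without a gene symbol were tested apart and are in no comparison.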

Results

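Gene expression was measured in mouse T cells of 3 genotypes, unstimulated and after 1 and 4 h of stimulation. MALT1 carries the antigen receptor signal to NF-kB as a scaffold, and it also cuts other proteins as a protease, its paracaspase activity. Cells with 1 working Malt1 allele (Malt1+/-, het here) were set beside cells whose only Malt1 allele carries the paracaspase mutation (Malt1PM/-, PM) and cells with no Malt1 (Malt1-/-, KO). The series is about telling a threshold function of MALT1 apart from its protease, and PM against KO sets the mutant allele beside no allele. Each of the 9 groups held 4 arrays, 36 in all, and the labels give each array an experiment number that recurs across the groups. The design text speaks of 3 biological replicates and the labels list 4, and neither says whether they are separate mice, so each p measures the spread between these samples. The labels describe total T cells taken by negative selection or purified CD4+ T cells, and PMA with ionomycin or plate-bound antibodies against CD3 and CD28 as stimulus, without saying which applies to these arrays. Between 7713 and 10291 of 25697 probes were detected per array, and the number of arrays per group limits the precision.

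Malt1 mRNA was higher in het than in KO at all 3 times and higher than in PM at 1 and 4 h. In het cells the log2 signal was 6.08 ± 0.35 (SD, n = 4) at 0 h, 6.75 ± 0.40 at 1 h and 7.29 ± 0.26 at 4 h. In PM cells it was 5.21 ± 0.37, 5.61 ± 0.43 and 6.10 ± 0.33 at the same times. In KO cells it was 4.79 ± 0.29 at 0 h, with the probe detected on 2 of 4 arrays, 4.66 ± 0.16 at 1 h with 0 of 4, and 5.82 ± 0.32 at 4 h with 4 of 4. The difference of KO from het was -1.29 at 0 h (log2, limma adjusted p = 0.00725), at least 3.44-fold lower at 1 h (adjusted p = 1.55e-06) and -1.47 at 4 h (adjusted p = 3.55e-05). That of PM from het was -1.13 at 1 h (adjusted p = 0.0184) and -1.20 at 4 h (adjusted p = 0.00136). The -0.86 of PM at 0 h did not pass (adjusted p = 0.191). PM against KO did not pass at any time, with 0.43 at 0 h, at least 1.57-fold at 1 h (adjusted p = 0.158) and 0.28 at 4 h (adjusted p = 0.801). Malt1 itself rose with stimulation, by 1.21 in het at 4 h (adjusted p = 2.99e-05), by 0.88 in PM (adjusted p = 0.00153) and by 1.03 in KO (adjusted p = 0.000349). Where the probe lies relative to the deleted part is not known, and a probe outside it would check nothing. Where no array of a group was above background, a fold is given as a lower bound, the brighter mean against the mean over the dim arrays of the lowest signal above background or the probe's own signal, whichever was higher.

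**Figure D1:**
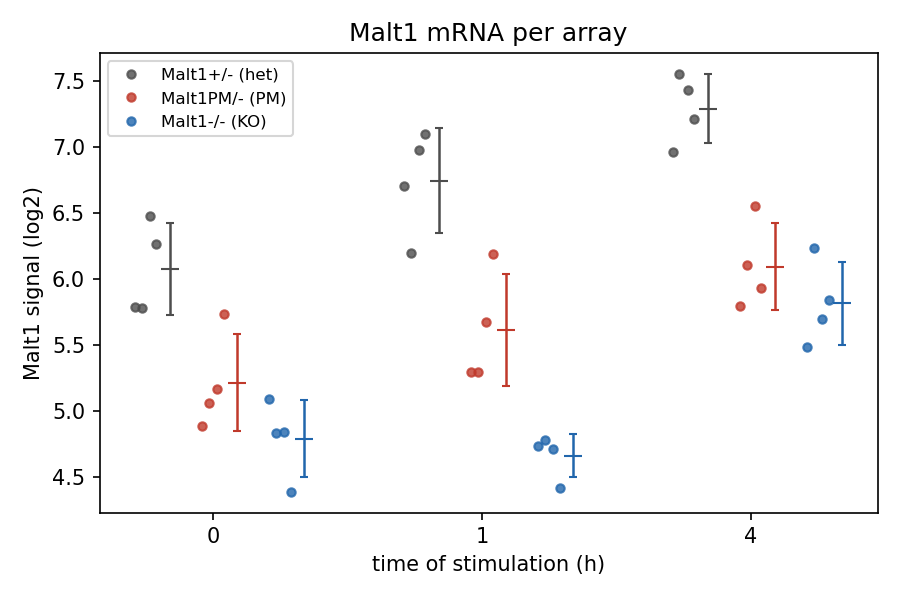
Malt1 signal (log2) on each of the 36 arrays against time of stimulation (h), with each group's mean and SD beside its 4 points. Every KO array at 0 and 1 h lies below every het array of its time, and the het means run from 6.08 at 0 h to 7.29 at 4 h.

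Stimulation for 1 h of het cells raised the transcription factor genes of the immediate early response. Egr2 went from 6.72 ± 0.19 to 12.05 ± 0.26 (log2, SD, n = 4), 40.1-fold (limma adjusted p = 1.39e-17). Crem rose by 5.15 ± 0.33 (log2, SE), and Irf4 by 4.48. The inflammatory cytokine Tnf rose 16.7-fold (adjusted p = 2.00e-15) and the chemokine Ccl4 by 4.78 ± 0.57. Among the falls were Ddit4 (-2.95), Slc40a1 (-2.07) and Txnip (-1.63). Of 7585 genes tested, 2139 passed, 960 up and 1179 down, and 397 rose and 141 fell at least 2-fold. The 4 and 4 values did not overlap for 2088 genes, where chance gives 217 (2.86%) if the arrays of both groups are interchangeable.

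By gene list, the AP-1 and immediate early genes moved by a mean of 2.23 in het at 1 h (25 measured, 20 rose, 0 fell, 20 rose adjusted over the list alone, camera adjusted p = 3.84e-20). The NF-kB targets moved by 1.57 (20 of 30 rose, 22 adjusted over the list alone, adjusted p = 5.57e-17), among them Tnfaip3 (3.70) and Nfkbid (3.65). All 12 measured mRNAs that Regnase-1 and Roquin degrade rose, with a mean of 2.62 (adjusted p = 3.25e-20). NFAT and calcium response genes rose by a mean of 1.25 (7 of 13 up, 1 down, adjusted p = 5.45e-06) and activation surface markers by 0.90 (9 of 18 up, adjusted p = 6.60e-06), with Ctla4 (2.94), Cd69 (2.84) and Icos (2.09). Cytokines and chemokines moved by 1.12 (10 of 23 rose, adjusted p = 5.70e-06, and 0.106 with an estimated correlation). Il2 is not analysed here. MALT1 complex and paracaspase substrate genes moved by 0.66 (14 measured, 8 rose, 1 fell, adjusted p = 0.00753), Bcl10 up (1.85) and Prkcq down (-0.77). Apoptosis and survival genes (0.68, adjusted p = 0.00753; 8 up, 3 down) included Cdkn1a (at least 8.57-fold up) and Casp9 (-1.11). Heat shock genes moved by 0.72 (adjusted p = 0.00105, and 0.117 with an estimated correlation). Of the 3 measured plasma cell markers Xbp1 (1.65) and Irf4 rose (list mean 1.91, adjusted p = 0.000363). Interferon-stimulated genes moved by -0.42 (6 of 27 down, adjusted p = 0.0278, and 0.489 with an estimated correlation), led by Ifit3 (-1.40) and Usp18 (-1.29), beside myeloid and dendritic cell markers at -0.54 (6 of 19 down, adjusted p = 0.0237, and 0.397 with an estimated correlation). The interferon call is lost in 1 of 8 fits without 1 array, and the myeloid call in 3 of 8 and in the authors' table.

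In het cells after 4 h Irf4 went from 6.08 ± 0.49 to 12.30 ± 0.12 (log2, SD, n = 4), 74.5-fold (limma adjusted p = 1.43e-19), and the chemokine Ccl4 rose 98.7-fold. The metabolic genes Bcat1, a branched-chain amino acid transaminase, and Hk2, a hexokinase, rose at least 33.9-fold and 27.3-fold, and the costimulatory receptor Tnfrsf9 at least 19.1-fold. Igfbp4 changed by -5.11 ± 0.22 (log2, SE, adjusted p = 2.37e-18), beside Itgb7 (-4.62), Txnip (-4.48), Pik3ip1 (-4.02) and Tsc22d3 (-4.00). In all 4186 of 7585 genes passed, 2040 up and 2146 down, 917 and 1075 of them at least 2-fold, and 3776 did not overlap between the 4 and 4 arrays.

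Ribosome biogenesis genes moved together in het at 4 h (1.82; 26 of 27 rose, 27 adjusted over the list alone, camera adjusted p = 1.87e-14, e.g. Mrto4 (2.55) and Ncl (2.50)), as did amino acid and one-carbon metabolism (1.65; 12 up, 1 down, adjusted p = 2.41e-06, e.g. Odc1 (3.89), Slc7a5 (3.20) and Srm (3.15)). NF-kB targets stood 2.03 above 0 h (23 up, 2 down, adjusted p = 1.54e-09, e.g. Tnf (4.01) and Ltb (-1.48)), the Regnase-1 and Roquin targets 2.62 (12 of 12 up, adjusted p = 8.54e-08), activation surface markers 1.95 (15 up, 1 down, adjusted p = 2.00e-07) and NFAT genes 1.51 (11 up, 1 down, adjusted p = 0.000312). Cytokines and chemokines moved by 1.94 (16 up, 1 down, adjusted p = 1.03e-05, and 0.138 with an estimated correlation), with Ccl3 (3.81), Cxcl10 (at least 7.72-fold) and Ifng (at least 5.68-fold). The immediate early genes stood 0.74 above 0 h (11 of 25 up, 2 down, adjusted p = 0.0342, and 0.435 with an estimated correlation), with Myc up by 3.30. Naive and quiescence genes moved by -1.65 (1 up, 12 down, adjusted p = 0.000144, and 0.0693 with an estimated correlation, e.g. Nsg2 (-3.64), Il7r (-3.40) and Klf2 (-2.72)). Cell marker lists moved down as well. These were T cell identity genes (-0.77; 2 up, 8 down, adjusted p = 0.0426, and 0.117 with an estimated correlation, e.g. Bcl11b (-2.15) and Cd3g (-1.44)), B cell markers (-1.17; 8 of 17 down, adjusted p = 0.0386, and 0.554 with an estimated correlation, e.g. Cd79b (-2.78)) and myeloid markers (-1.27; 12 of 19 down, adjusted p = 0.00168, and 0.338 with an estimated correlation, e.g. Lyz2 (-3.81) and S100a8 (-2.59)). Regulatory T cell markers, some shared with the activation list, moved by 0.98 (9 up, 5 down, adjusted p = 0.0402, and 0.435 with an estimated correlation). The T cell identity and B cell calls are lost in 3 of 8 fits without 1 array each, and the first also over replicates 1 to 3.

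In PM cells at 1 h Egr2 rose 26.1-fold, from 7.06 ± 0.13 to 11.76 ± 0.46 (log2, SD, n = 4, limma adjusted p = 5.43e-16), beside Crem (4.79), Irf4 (3.80) and Tnfaip3 (3.53), and Nr4a2 at least 13.5-fold, while Ddit4 fell by 2.40. At 4 h Xcl1 rose 52.1-fold and Irf4 48.7-fold (adjusted p = 3.22e-18), with Ccl3 up by 4.12 ± 0.49 (SE), and Igfbp4, Itgb7 and Txnip changed by -4.89, -4.18 and -3.65. At 1 h 1777 genes passed (782 up, 995 down; 1569 without overlap) and at 4 h 3875 (1817 up, 2058 down; 3315 without overlap). At 4 h NF-kB targets stood 1.71 above 0 h (24 of 30 rose, adjusted p = 1.66e-09), Regnase-1 and Roquin targets 2.24 (12 of 12, adjusted p = 1.85e-08), ribosome biogenesis 1.62 (26 of 27, adjusted p = 3.73e-15) and cytokines and chemokines 2.27 (19 of 23, adjusted p = 4.09e-09). At 1 h the ribosome biogenesis list moved by 0.23 (4 of 27 rose, adjusted p = 0.0167, and 0.315 with an estimated correlation), and with the arrays scaled to a common median in place of quantile normalization its score fell by 0.0685.

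KO cells also switched on the immediate early genes. At 1 h Crem rose 43.8-fold and Egr2 29.1-fold, from 7.01 ± 0.26 to 11.88 ± 0.54 (log2, SD, n = 4, limma adjusted p = 2.03e-16), beside Ccl4 (4.51) and Irf4 (4.45). At 4 h Irf4 rose 67.5-fold (adjusted p = 4.30e-19), Xcl1 at least 37.5-fold, Rgs16 at least 27.8-fold and Akr1c18, a steroid-metabolizing reductase, at least 20.3-fold, while Igfbp4 (-5.20), Itgb7 (-4.28) and Txnip (-3.51) fell. At 1 h 2133 genes passed (942 up, 1191 down; 2013 without overlap) and at 4 h 3502 (1684 up, 1818 down; 3228 without overlap). NF-kB targets stood 1.53 above 0 h at 4 h (20 of 30 rose, adjusted p = 1.35e-08), Regnase-1 and Roquin targets 2.10 (10 of 12, adjusted p = 1.63e-08), ribosome biogenesis 1.5 (26 of 27, adjusted p = 4.24e-16) and cytokines and chemokines 1.43 (17 of 23, adjusted p = 2.08e-05, and 0.163 with an estimated correlation). The ribosome biogenesis score at 1 h fell by 0.0575 with median scaling, where the list mean was 0.26 (adjusted p = 0.0105, and 0.302 with an estimated correlation). Median scaling also shifts the median gene, by -0.18 and -0.12 in het, -0.32 and -0.11 in PM and -0.32 and -0.12 in KO (1 h, then 4 h). Calls with it were 594 (300 up, 294 down), 600 (186 up, 414 down) and 787 (211 up, 576 down) at 1 h in het, PM and KO, and 2699 (1063 up, 1636 down), 2273 (869 up, 1404 down) and 1746 (659 up, 1087 down) at 4 h.

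**Figure D2:**
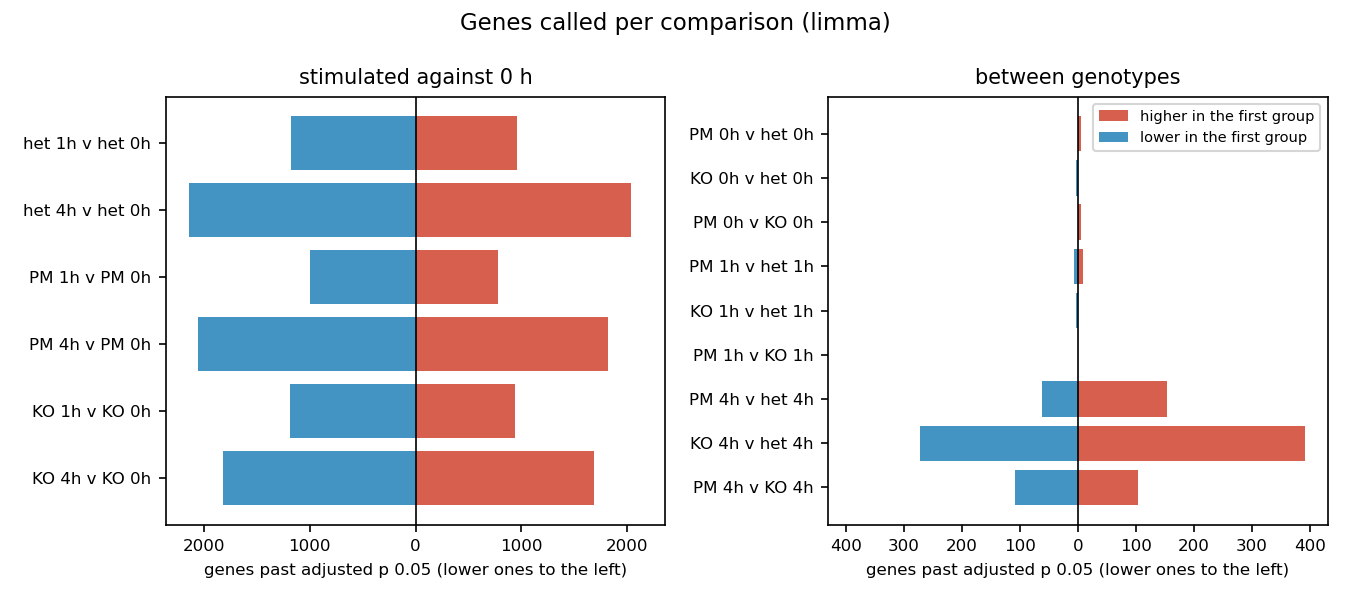
Number of genes that passed limma's adjusted p of 0.05 in each direction, stimulated against 0 h on the left and between genotypes on the right; bars to the right are genes higher in the first group named. Stimulation calls run from 1777 to 4186 genes, and the genotype comparisons hold at most 16 genes at 0 and 1 h and 213 to 663 at 4 h.

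To compare the size of the responses, genes were chosen by their mean response over the 3 genotypes, so that no genotype was favoured. At 4 h the 747 rising genes rose by a mean of 1.83 ± 0.07 in het (log2, SD, n = 4), 1.64 ± 0.11 in PM and 1.49 ± 0.07 in KO. KO kept 81.4% of the het rise (exact permutation p = 0.0286, adjusted 0.114) and 79.8% of the het fall over 895 genes (exact p = 0.0286, adjusted 0.114), every KO array short of every het array in both. For PM the rise gave an exact p of 0.0857 against het, and the fall, of which PM kept 86.1%, an exact p of 0.0571. PM against KO gave an exact p of 0.0571 for the rise. At 1 h PM kept 90.9% and KO 97.1% of the rise over 366 genes, and 87.5% and 102% of the fall over 128 genes, with exact p from 0.229 to 0.686. The smallest exact p of 4 against 4 is 0.0286, and no adjusted value over the 8 tests passed. All 4 arrays of a group were set against the same 0 h mean. The SD and the exact p thus hold only the spread of the stimulated arrays. Neither the spread at 0 h nor the replicate numbers enter them.

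**Figure D3:**
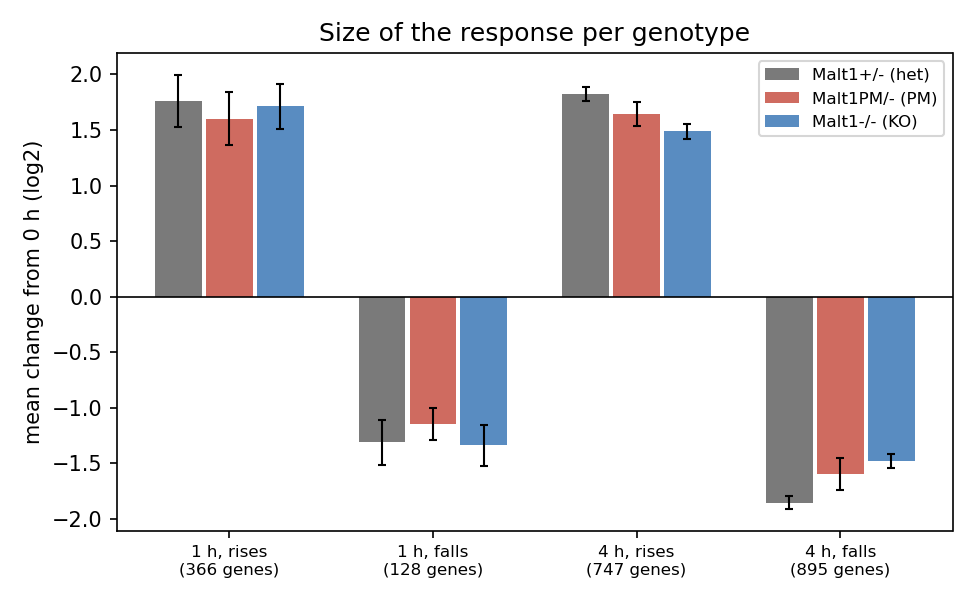
Mean change from 0 h (log2) over genes that rise or fall by at least 1 on average over the genotypes, per genotype and time. Bars are means of 4 arrays and error bars are SD over the stimulated arrays, without the spread at 0 h. At 4 h the KO bars reach 81.4% of the het rise and 79.8% of the het fall.

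Before stimulation PM cells differed from het in 6 genes. Gvin1, an interferon-inducible GTPase, stood at 9.38 ± 0.44 in PM and 7.88 ± 0.29 in het (log2, SD, n = 4), 2.82-fold higher (limma adjusted p = 0.00553). The actin-severing gene Scin was at least 1.89-fold higher (adjusted p = 0.0217), and the interferon-inducible Tgtp1 and the calcineurin subunit Ppp3cc were 2.00-fold and 2.15-fold higher. With Smpdl3b (1.01) and Mgarp (at least 1.43-fold) these made up all 6 calls, 0 of them lower. The interferon-stimulated list was higher by 0.54 (6 members adjusted over the list alone, 0 over all genes, camera adjusted p = 1.05e-16, and 0.0693 with an estimated correlation), among them Oasl2 (1.29), Gbp2 (1.25) and Igtp (1.05). Its score was 8.08 ± 0.32 in PM and 7.54 ± 0.07 in het, higher in 4 of 4 replicate numbers (exact permutation p = 0.0286, adjusted 0.80 over the 28 lists, and 0.171 with median scaling). Myeloid markers moved the other way, by -0.32 (0 of 19 fell, adjusted p = 6.06e-05, and 0.419 with an estimated correlation), as did B cell markers (-0.23, adjusted p = 0.0382, and 0.652 with an estimated correlation), a call that is lost in the authors' table and in 3 of 8 fits without 1 array and turns to 0.02 without het replicate 3. An unadjusted limma p under 0.05 was reached by 271 genes, and 173 did not overlap where chance gives 217. That number takes the arrays as interchangeable, and differences between replicates can lower it. The calls number 2 without het replicate 1 or PM replicate 4, 3 without het replicate 2 and 0 without PM replicate 3. They number 12 (11 up, 1 down) in the authors' table, 15 (13 up, 2 down) without background correction, 36 (22 up, 14 down) with array weights, and 0 with only the arrays of these groups in the fit.

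KO cells before stimulation stood apart from het in Malt1 and a few further genes. Ppic, a cyclophilin on the chromosome of Malt1 (GRCm38.p6), was at 6.68 ± 0.33 in KO and 7.97 ± 0.36 in het (log2, SD, n = 4, limma adjusted p = 0.000809), Arsb was 2.00-fold lower, and H2-M2, detected on 1 of 4 KO arrays and 4 of 4 het arrays, was lower (adjusted p = 0.0405). These and Malt1 were all 4 calls. Regulatory T cell markers differed by a mean of -0.30 (18 measured, camera adjusted p = 4.07e-09, and 0.0455 with an estimated correlation, fry adjusted p = 0.459). None passed the threshold alone over all genes and 2 did adjusted over the list alone, Foxp3 (-0.97) and Nt5e (-0.66). Foxp3 is the master factor of regulatory T cells. B cell markers moved by -0.40 (adjusted p = 1.66e-05, and 0.471 with an estimated correlation) and CD8 T cell markers by -0.30 (adjusted p = 0.0217, and 0.471 with an estimated correlation; Ctsw -1.06), and heat shock genes by 0.16 (adjusted p = 0.0247, and 0.471). These 3 calls are lost in 2, 3 and 3 of 8 fits without 1 array, and the last also in the authors' table and over replicates 1 to 3. PM against KO at 0 h gave 5 calls, all higher in PM: Gvin1 (1.38 ± 0.25, SE, adjusted p = 0.0141), Nrp1 (1.03), Tiam1 (0.98), Scin (at least 1.86-fold) and Mgarp (at least 1.40-fold). There regulatory T cell markers were 0.30 higher in PM (adjusted p = 3.51e-06, and 0.0838 with an estimated correlation) and interferon-stimulated genes 0.46 (adjusted p = 8.08e-14, and 0.0743 with an estimated correlation), with myeloid markers -0.28 (adjusted p = 0.000324, and 0.369 with an estimated correlation) and CD8 markers 0.40 (adjusted p = 0.0360, and 0.482). The myeloid call is lost in 1 and the CD8 call in 4 of 8 fits without 1 array, the latter also in the authors' table and over replicates 1 to 3. KO against het has 2 calls without KO replicate 2, 3 or 4, 1 without het replicate 3 or 4, and 2 with median scaling, 0 of them shared. PM against KO has 8 without KO replicate 1, 3 without KO replicate 3, 1 without KO replicate 4 or PM replicate 3, 25 (24 up, 1 down) with the replicate number as a block, 45 (28 up, 17 down) with array weights and 9 (7 up, 2 down) in the authors' table.

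At 1 h Tnf separated both mutants from het. It stood at 9.48 ± 0.20 in PM, 9.53 ± 0.42 in KO and 10.73 ± 0.45 in het (log2, SD, n = 4, limma adjusted p = 0.0113 for PM and 0.0102 for KO). The T helper cytokine gene Il4 was higher in PM than in het, 3.11-fold (adjusted p = 0.0184). So were the interferon-inducible Gvin1 (1.27), Igtp (1.26) and Ifi47 (1.12) and Scin (at least 1.72-fold). PM against het gave 16 calls (9 up, 7 down), with 334 genes at an unadjusted limma p under 0.05 and 170 without overlap. Beside Tnf the falls included Malt1, Ppic (-0.90) and Arsb (-0.76). Apol9b, detected on 0 of 4 PM and 4 of 4 het arrays, was at least 1.33-fold lower. KO against het gave 4, namely Malt1, Tnf, Ppic (-1.24) and Arsb (2.00-fold lower). PM against KO gave 1, Gvin1 (2.83-fold higher, adjusted p = 0.0104).

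Interferon-stimulated genes were 0.61 higher in PM than in het at 1 h (3 of 27 rose, 10 adjusted over the list alone, camera adjusted p = 1.63e-20, and 0.0270 with an estimated correlation). They were 0.55 higher than in KO (camera adjusted p = 5.88e-17, and 0.0498 with an estimated correlation, fry adjusted p = 0.0754). Regnase-1 and Roquin targets, in part also on the NF-kB and immediate early lists, were lower in both mutants. Their means were -0.35 in PM (adjusted p = 0.000286, and 0.153 with an estimated correlation) and -0.48 in KO (adjusted p = 1.47e-10, and 0.00394, with 4 of 12 lower adjusted over the list alone). NF-kB targets stood at -0.15 in PM (adjusted p = 0.00766, and 0.484 with an estimated correlation) and -0.28 in KO (adjusted p = 9.39e-09, and 0.0634 with an estimated correlation). Immediate early genes stood at -0.23 in PM (adjusted p = 0.000834, and 0.283 with an estimated correlation) and -0.21 in KO (adjusted p = 0.000482, and 0.187 with an estimated correlation). In KO against het, regulatory T cell markers (-0.24, adjusted p = 2.12e-05, and 0.101 with an estimated correlation), cytokines (-0.24, adjusted p = 0.000782, and 0.355) B cell markers (-0.39, adjusted p = 4.95e-05, and 0.385) and CD8 markers (-0.30, adjusted p = 0.00761, and 0.355) were also lower, and in PM against het myeloid markers (-0.29, adjusted p = 0.00250, and 0.484). Cell cycle genes were 0.18 higher in PM than in KO (adjusted p = 0.00649, and 0.0498 with an estimated correlation), with 0 of 18 members past the threshold, and the call is lost in the authors' table, over replicates 1 to 3 and in 3 of 8 fits without 1 array. Without 1 array the NF-kB and myeloid calls of PM are lost in 3 of 8 fits each, the latter also in the authors' table, and the cytokine, B cell and CD8 calls of KO in 2, 2 and 4 of 8. These 1 h counts are unstable. Over replicates 1 to 3 PM against het has 6 calls, 1 up and 5 down. With the replicate number as a block they become 36 (25 up, 11 down), 20 (3 up, 17 down) and 42 (34 up, 8 down) for PM against het, KO against het and PM against KO. Median scaling leaves 2 PM against het calls with the median gene at -0.12, and gives 4 for KO against het, 1 of them shared, with the median gene at -0.21. PM against het has 7, 3 and 2 calls without het replicates 1, 3 and 4 and 9 and 3 without PM replicates 1 and 3. KO against het has 9 without het replicate 2 and 2 without KO replicate 2, and PM against KO has 3, 3 and 0 without PM replicates 1, 2 and 3 and 4, 0, 0 and 3 without KO replicates 1 to 4, and 4 (3 up, 1 down) in the authors' table.

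At 4 h more genes were higher in PM than in het than were lower, with cytokine and interferon genes among the higher ones. Malt1 mRNA was 2.29-fold lower in PM there, so a lower amount and the mutation are not told apart. Il4 stood at 8.57 ± 0.28 in PM and 5.81 ± 0.85 in het (log2, SD, n = 4), 6.75-fold higher (limma adjusted p = 2.84e-06). Usp18, which damps interferon signalling and is itself induced by it, was 2.20 ± 0.35 higher (SE, adjusted p = 0.000164), the antigen-presentation gene H2-DMa 2.42 ± 0.34 and the chemokine Ccl1 1.92 ± 0.33. The growth factor Pdgfb was 8.99-fold lower (6.11 ± 0.77 against 9.28 ± 0.47, adjusted p = 5.84e-07), and Tnf lay at 9.65 ± 0.40 against 10.67 ± 0.37 (adjusted p = 0.00502). Of 7585 genes 215 passed, 154 up and 61 down, and 456 did not overlap where chance gives 217. The other rises included Ly6c1 (2.18), Oasl2 (1.82) and Gbp7 (1.67), Gbp11 (at least 2.28-fold) and Il12rb2 (at least 2.16-fold), and the falls Id3 (-1.46), Tnfsf14 (-1.31), Tfrc (-1.20) and Irak2 (-1.18).

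Interferon-stimulated genes were 1.00 higher in PM than in het at 4 h, and 14 of 27 rose, 20 adjusted over the list alone (camera adjusted p = 1.44e-28), with Ifit3 (1.82), Irf7 (1.35) and Gbp2 (1.25). The score was 7.85 ± 0.32 in PM and 6.85 ± 0.38 in het, higher in 4 of 4 replicate numbers (exact permutation p = 0.0286, adjusted 0.114). Cytokines and chemokines were 0.35 higher (6 up, 2 down, adjusted p = 0.00438, and 0.320 with an estimated correlation), with an exact p of 0.143 for the score. Beside Il4 and Ccl1 the rises were Il3 (1.38), Csf2 (1.23) and Ifng (1.21) and Il21 (at least 1.44-fold), and the falls were Tnf and Tnfsf14. NFAT genes were 0.43 higher (3 up, 5 up and 2 down adjusted over the list alone, adjusted p = 0.00770, and 0.146 with an estimated correlation). That list shares Il4, Il3 and Csf2 with the cytokine list. Effector genes were 0.31 higher (adjusted p = 0.00438, and 0.291, 2 up, 1 down) and naive genes 0.20 (adjusted p = 0.0245, and 0.291, e.g. Klf3 (1.12) and Il7r (0.82)). NF-kB targets went the other way, -0.18 (3 of 30 down, Bcl2l1 (-2.02) and Nfkbid (-0.88) and Tnf, adjusted p = 0.0248, and 0.391 with an estimated correlation). Beside them lay Regnase-1 and Roquin targets at -0.36 (3 of 12 down, adjusted p = 0.00183, and 0.146, e.g. Tnfrsf4 (-0.94)), amino acid metabolism at -0.23 (adjusted p = 0.0245, and 0.146) and ribosome biogenesis at -0.14 (adjusted p = 0.00694, and 0.291). Immediate early genes, lower in PM at 1 h, were 0.29 higher (adjusted p = 0.0366, and 0.391), a call lost in the authors' table and in 4 of 8 fits without 1 array. The effector, naive, amino acid and ribosome calls are lost in 1, 4, 3 and 1 of 8, and the naive call also over replicates 1 to 3 and with the replicate number as a block. Without het replicate 3 or PM replicate 1 the count is 143 or 128, and the NF-kB call is lost without het replicate 3 or PM replicate 4 and the cytokine call without het replicate 2 or PM replicate 3. With the replicate number as a block 361 genes pass (250 up, 111 down), with median scaling 31 (22 up, 9 down), without background correction 203 (123 up, 80 down) and over replicates 1 to 3 107 (75 up, 32 down).

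**Figure D4:**
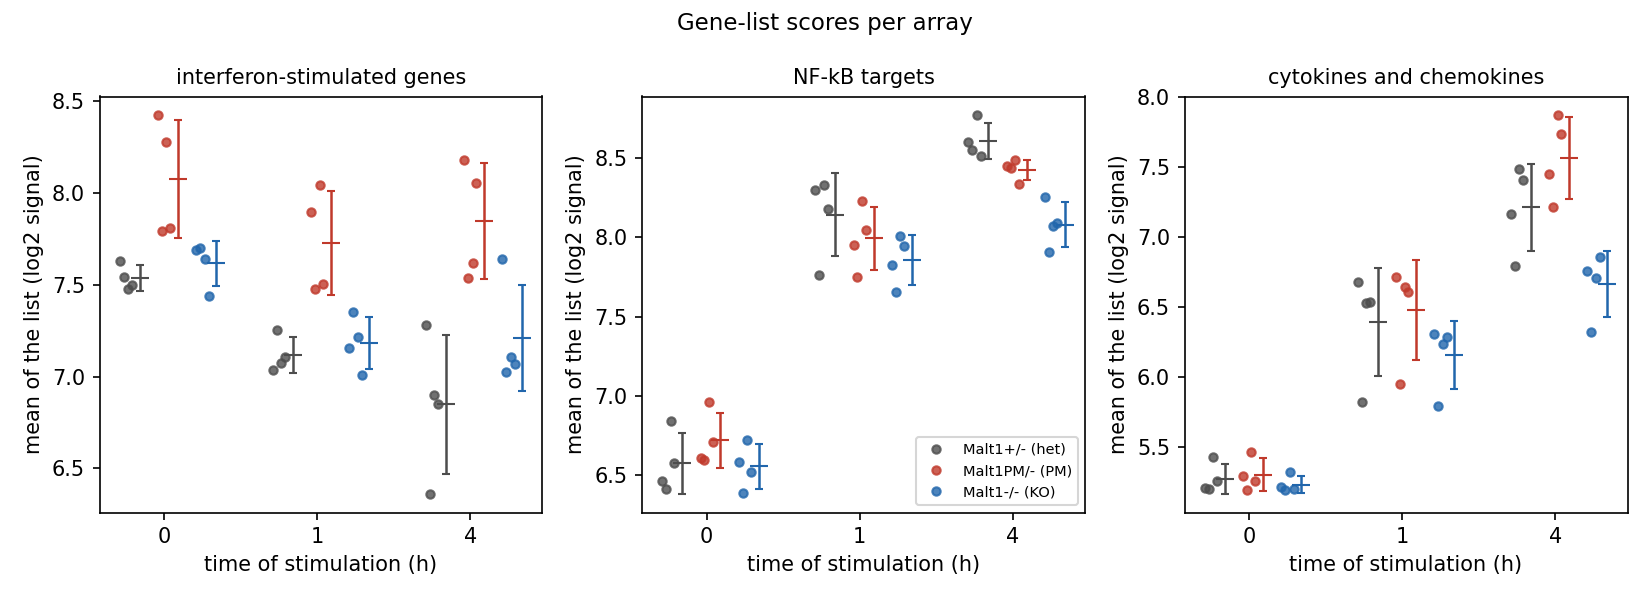
Mean log2 signal over the measured members of 3 gene lists on each of the 36 arrays against time of stimulation (h), with each group's mean and SD. At 4 h the interferon score is 7.85 in PM, 7.21 in KO and 6.85 in het, the NF-kB score 8.43, 8.08 and 8.61, and the cytokine score 7.57, 6.66 and 7.21.

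KO against het had more calls at 4 h than PM against het, and NF-kB targets lay lower. The epithelial anchoring gene Lad1 stood at 5.68 ± 0.70 in KO and 8.92 ± 0.80 in het (log2, SD, n = 4), 9.40-fold lower (limma adjusted p = 2.31e-09), and Pdgfb was 9.08-fold lower. The survival gene Bcl2l1, an NF-kB target, stood at 5.43 ± 0.73 against 8.21 ± 1.37 (adjusted p = 0.000198), the costimulatory receptor gene Tnfrsf4 was -1.82 ± 0.19 (SE, adjusted p = 6.52e-08) and the cytokine-signalling inhibitor Cish -2.08 ± 0.26. Cldn10, a claudin, was 5.76-fold higher (8.47 ± 0.30 against 5.95 ± 0.28, adjusted p = 3.01e-10), beside Akr1c18 (2.34), Dhrs1 (2.07), Dgka (1.41) and Mapk14 (1.38). Further falls were Sytl3 (-2.44), Tnfsf14 (-2.35), Ccl4 (-2.14) and Tfrc (-1.59). Of 7585 genes 663 passed, 391 up and 272 down, 53 and 55 of them at least 2-fold, and 1014 did not overlap where chance gives 217.

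NF-kB targets were -0.53 in KO against het at 4 h (8 of 30 fell, 9 adjusted over the list alone, none rose, camera adjusted p = 2.04e-06, and 0.0839 with an estimated correlation), with Map3k8 (-1.31), Tnf (-1.24), Lta (-1.05), Ier3 (-1.04), Nfkbid (-1.03) and Il2ra (-0.73). The score was 8.08 ± 0.14 in KO and 8.61 ± 0.11 in het (exact permutation p = 0.0286, adjusted 0.133, and 0.229 with median scaling). Regnase-1 and Roquin targets moved by -0.66 (5 down, Egr1 up by 0.82, adjusted p = 3.32e-05, and 0.0590 with an estimated correlation), cytokines and chemokines by -0.55 (4 down, 1 up, adjusted p = 0.000817, and 0.329) and activation surface markers by -0.33 (7 down, 1 up, adjusted p = 0.00733, and 0.264, e.g. Cd200 (-1.37), Tnfrsf18 (-1.18) and Cd28 (1.18)). Growth genes moved down too, amino acid and one-carbon metabolism by -0.35 (3 of 17 down, 6 adjusted over the list alone, adjusted p = 0.000817, e.g. Slc7a5 (-0.58) and Shmt2 (-0.52)) and ribosome biogenesis by -0.27 (2 of 27 down, adjusted p = 0.000192, and 0.214 with an estimated correlation). T cell identity genes, which fall with stimulation, were 0.22 higher (6 up, 2 down, adjusted p = 0.00733, and 0.0590, e.g. Cd3g (0.91), Bcl11b (0.81) and Thy1 (-1.04)). NK cell markers were 0.39 higher (7 of 7 above 0, adjusted p = 0.168). Interferon-stimulated genes were 0.36 higher with 1 member past the threshold (Irgm1 (0.40), adjusted p = 0.00560, and 0.573), a call lost without het replicate 2 or KO replicate 1. Median scaling leaves 73 calls and turns the split (18 up, 55 down), no background correction gives 708 (327 up, 381 down), and the replicate number as a block 1153 (657 up, 496 down). Ccl4 no longer passes without het replicate 3.

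PM against KO at 4 h sets the mutant allele beside none. Il4 was 7.76-fold higher in PM (8.57 ± 0.28 against 5.61 ± 0.37, log2, SD, n = 4, limma adjusted p = 1.18e-06), Il3 by 2.14 ± 0.26 (SE, adjusted p = 2.54e-06), Ifng by 1.98 ± 0.33 (adjusted p = 0.000272) and the growth factor Csf2 by 1.41. Cish, Lad1 and Usp18 were higher by 2.18, 2.15 and 1.74. Lower in PM were Cldn10 (-2.66), Akr1c18 (-2.21), Sytl2 (-1.99), Dhrs1 (-1.78) and Klrd1 (-1.26). In all 213 genes passed (104 up, 109 down; 528 without overlap). Cytokines and chemokines were 0.91 higher in PM (7 of 23 rose, 9 adjusted over the list alone, none fell, camera adjusted p = 1.08e-14), with a score of 7.57 ± 0.29 against 6.66 ± 0.24 (exact permutation p = 0.0286, adjusted 0.133, and 0.0571 with median scaling). Interferon-stimulated genes were 0.64 higher (3 rose, 10 adjusted over the list alone, adjusted p = 1.42e-13, and 0.0863 with an estimated correlation), NF-kB targets 0.35 (Il2ra (0.59) up, Tnfrsf9 (-0.61) down, adjusted p = 3.95e-05, and 0.142) and effector genes 0.36 (3 up, adjusted p = 0.00187, and 0.238, e.g. Gata3 (1.39) and Tbx21 (1.09)). NK cell markers were -0.37 (adjusted p = 0.0437, and 0.292; 1 of 7, Klrd1, passed), a call lost in the authors' table and in 4 of 8 fits without 1 array. Median scaling leaves 32 calls (25 up, 7 down), replicates 1 to 3 142 (54 up, 88 down), and the count is 114 without PM replicate 3 and 136 without KO replicate 2.

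PM and KO shared part of their distance from het at 4 h. Of the called genes 60 were higher than het in both (7.94 for independent lists), 47 lower in both (2.19), and 0 called in opposite directions. Both comparisons use the same het arrays, which alone favours shared calls over opposite ones. Independent lists are thus too low a baseline, and no such count is given for shared het arrays. Pdgfb, Tnf, Tfrc, Tnfsf14, Sytl3, Id1, Ppic and Malt1 are among the shared falls. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.634, against 0.502 simulated for shared het arrays with no effect. The covariance was 0.0653 against 0.0294 simulated, a difference of 0.0360, and with the het arrays split between the comparisons it was 0.0388 (r = 0.304, range 0.215 to 0.470). At 0 and 1 h the observed covariance was 0.0188 and 0.0204, below the simulated value, so the simulation does not match these arrays closely. With the het arrays split it was -0.00347 and -0.00542 there.

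Differences between the responses were tested as such. Sizes are given only for genes detected on at least 2 of 4 arrays in each of the 4 groups compared. At 4 h the response of Il4 was larger in PM than in het (limma adjusted p = 0.0266) and in KO (adjusted p = 0.00894), from a start near background, with 0 of 4 het and KO arrays at 0 h detected. Pdgfb rose by 4.36 in het (log2), and the response of PM differed from that by -3.16 ± 0.48 (SE, adjusted p = 0.00182). PM differed from het in 10 genes (7 up, 3 down), also Sft2d2 (1.35) and Klhl6 (1.02) above, with Il12rb2 and Gbp11 near background at 0 h, and Id1 below. KO differed in 151 (97 up, 54 down). Of these Akr1c18, Dhrs1 (2.10), Cldn10 (1.92), Klrd1 (1.75) and Dgka (1.44) responded more positively, and Lad1, Pdgfb, Tnfsf14, Bcl2l1 (-2.56), Tfrc (-1.64) and Cish (-1.57) less. PM and KO differed in 28 (8 up, 20 down), Il3 (adjusted p = 0.00250), Csf2, Jaml (1.57) and Gpr183 (1.23) above and Akr1c18, Cldn10 (-2.23), Dhrs1 (-1.83) and Angptl4 (-1.72) below. The cytokine response was 0.83 larger in PM than in KO (3 of 23 passed, 6 adjusted over the list alone, camera adjusted p = 8.28e-14, and 0.0437 with an estimated correlation, fry adjusted p = 0.0531). This mean includes members near background at 0 h. Against het, the NF-kB response was -0.33 in PM (adjusted p = 0.000426, and 0.194 with an estimated correlation) and -0.51 in KO (adjusted p = 2.99e-05, and 0.201), and the interferon response 0.46 in PM (adjusted p = 5.10e-06, and 0.194), where the list moved by -0.69 in het and -0.23 in PM, a smaller fall. In KO the response differed from het by 0.52 for NK cell markers (adjusted p = 0.0381, and 0.412) and -0.31 for heat shock and handling stress genes (adjusted p = 0.0381, and 0.412). These calls are lost in 5 and 7 of 16 fits without 1 array and both in the authors' table, and the latter also over replicates 1 to 3. The response of immediate early genes was 0.35 in PM against het (adjusted p = 0.00836, and 0.300), lost in 3 of 16. The PM count is 6 without het replicate 2 or 4 at 0 h, PM replicate 3 at 0 h or PM replicate 1 at 4 h, and 20 without PM replicate 3 at 4 h, and Il4 itself no longer passes in 11 of 16 such fits. The authors' table gives 24 (13 up, 11 down) and no background correction 20 (8 up, 12 down). The KO count is 90 or 99 without het replicate 3 or 4 at 4 h and 99 without KO replicate 2 at 0 h, and median scaling gives 11 (2 up, 9 down) and no background correction 198 (96 up, 102 down). The PM against KO count falls to between 9 and 18 without any of 9 arrays (PM replicates 1, 2 and 4 at 0 h, PM 1 and 3 at 4 h, KO 2 and 3 at 0 h, KO 2 and 4 at 4 h), and median scaling leaves 3 (3 up, 0 down).

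At 1 h limma called 0 genes for the difference of PM from het, 0 for KO from het and 0 for PM from KO, with 56, 44 and 68 genes at an unadjusted p under 0.05. In the same order the authors' table gave 2, 0 and 2 calls and the replicate number as a block 0, 1 and 0. By list, the NF-kB response at 1 h was -0.29 in PM (camera adjusted p = 1.22e-06, and 0.151 with an estimated correlation) and -0.26 in KO (adjusted p = 1.40e-05, and 0.254), and that of Regnase-1 and Roquin targets -0.37 in PM (adjusted p = 0.000128, and 0.151) and -0.33 in KO (adjusted p = 0.000908, and 0.254, lost in 2 of 16 fits without 1 array). Of the list calls, 43 of 80 between stimulated and resting cells held with an estimated correlation, 8 of 67 between genotypes and 1 of 27 between responses. Those 8 are interferon-stimulated genes in PM over het at 1 and 4 h and over KO at 1 h, cell cycle genes in PM over KO at 1 h, regulatory T cell markers in KO below het at 0 h, Regnase-1 and Roquin targets in KO below het at 1 h, amino acid metabolism in KO below het at 4 h and cytokines in PM over KO at 4 h, where the difference of responses held too. The rotation test fry, which asks only whether a list's genes move one way and compares them with no other genes, held 80, 20 and 4 of these calls.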

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

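The test of myeloid markers, the interferon tests at 0 and 1 h, the fits on replicates 1 to 3 alone, the checks given beside the 8.18% and the gene distances were chosen after the results were seen, and the other tests of this part were planned. Single arrays stood far from the other 3 of their group in 5 of 72 groups of scores, where chance gives about 1 in 20. The cytokine score was low at 5.95 in PM at 1 h replicate 2 (others 6.61 to 6.71) and at 5.79 in KO at 1 h replicate 2 (others 6.23 to 6.30), and high at 5.32 in KO at 0 h replicate 3 (others 5.19 to 5.21). The Regnase-1 and Roquin score was high at 6.75 on that last array (others 6.51 to 6.54). The interferon score of KO at 4 h was high at 7.64 in replicate 1 (others 7.02 to 7.11). The difference between responses at 4 h was tested directly and passed for 10 genes between PM and het, 151 between KO and het and 28 between PM and KO, and for the cytokine list between PM and KO (0.83, log2, PM over KO). Of 647 detected probes without a gene symbol, which no comparison uses, 318 passed in het at 4 h against 0 h (160 up, 158 down) and 37 in KO against het at 4 h (23 up, 14 down).

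Interferon-stimulated genes stood higher in PM than in het at 0, 1 and 4 h, with score differences of 0.54, 0.61 and 1.00 (log2). PM lay above het in each of the 4 replicate numbers at every time, but the same numbers recur over the times. The differences of replicates 1 to 4 were 0.79, 0.25, 0.80 and 0.32 at 0 h. At 1 h they were 0.86, 0.22, 0.97 and 0.40. RNA of myeloid cells in the PM samples would raise their markers, but the marker means lay below 0 at all 3 times. They were -0.32 ± 0.06, -0.29 ± 0.07 and -0.13 ± 0.06 (SE over members, which move together and are not replicates). With an estimated correlation the list did not pass at 0 and 1 h (camera adjusted p = 0.419 and 0.484), and at 4 h 6 of 19 members lay above 0. Such RNA is argued against only by the lack of a rise. The dimmer arrays of replicate 4 are argued against as well, with 0.93 over replicates 1 to 3 at 4 h and 0.62 at 0 h, the lower of 0 and 1 h, and so is the scaling of the arrays at 4 h, with 1.05 under median scaling. At 0 and 1 h median scaling gives 0.56 and 0.47, each with an exact p of 0.171 in place of 0.0286, so a part of the scaling there stays open. A response of the PM cells, or of the mice they came from, to interferon may explain the pattern, and it stays open and untested.

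KO kept 81.4% of the het rise at 4 h and 79.8% of the fall. A smaller share of responding cells in the KO cultures would shrink every response, though on the log2 scale not all by the same percent. Of 391 response genes called between KO and het, however, 32 went against the smaller response (8.18%, and 7.26 to 10.6% in the fits without 1 array). At most 5% was set for that explanation. Genes are not independent, so no interval is given. Igfbp4 and Golm1, of the 32, lay at -0.76 and -0.62 (log2) in KO against het at 0 h, where neither passed. The response itself differed that way for 26 of the 32 at an unadjusted limma p under 0.05 and for 7 at an adjusted one (Akr1c18, Bdh2, Cd226, Creb3l2, Ipcef1, Mmd and Themis). Of 92 response genes whose response difference passed these 7 went against the smaller response (7.61%, and 5.13 to 10.1% without 1 array), so that a smaller share is argued against as the whole cause only. The dimmer arrays of replicate 4 are argued against by 80.4% over replicates 1 to 3. A KO state nearer to the stimulated one at 0 h is argued against as well, since KO minus het over the rising genes at 0 h is 1.27% of the rise that KO lacks. A weaker signal without MALT1 could produce the pattern, as could a part played by fewer responding cells beside other changes, and both stay open.

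For 52 genes in KO and 141 in PM the mean difference from het over the 3 times passed and neither response differed from that of het at an unadjusted limma p under 0.05, which does not show equal amounts at each time. Malt1, which met this in PM, is left out of these counts. Alleles of another strain linked to the targeted locus may account for a part in KO, where 4 of 52 lie on the chromosome of Malt1 (GRCm38.p6) with 1.13 expected (one-sided Fisher exact p = 0.0261). These are Ppic, Mzb1, Slc12a2 and Nars, with 225, 552, 153 and 14 annotated genes between them and Malt1. With only 4 genes the excess may rest on Mzb1, and it was not tested without that gene. Mzb1 is also a B cell gene. It stood at -1.21, -0.84 and -0.80 (log2 at 0, 1 and 4 h, KO against het), and B cell markers at -0.40, -0.39 and -0.11, the calls at 0 and 1 h being lost with an estimated correlation (adjusted camera p = 0.471 and 0.385), so a part of fewer B cells stays open. In PM 4 of 141 lie there with 3.07 expected (exact p = 0.369). An effect of MALT1 on these genes stays open and was not tested.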

How the results depend on the processing

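The fits on replicates 1 to 3 alone were chosen after the data were seen. Named genes kept direction in all settings and left-out arrays (0 reversed). Between 2 groups, however, they were chosen for values that do not overlap. Fits of the same signals that leave out or weight arrays could thus not reverse them, and only other scalings or probes could. For stimulated against resting cells 28 to 30 of 30 per comparison passed in every setting. For PM against het, KO against het and PM against KO at 4 h 10, 25 and 17 of 30 passed in every setting. Between genotypes at 0 and 1 h that held for 1 named gene, in KO against het at 1 h. Of 80 list calls for stimulation 75 held with the replicate number as a block, 75 in the authors' table, 74 over replicates 1 to 3 and 66 in every fit without 1 array. Of 67 between genotypes these were 63, 53, 54 and 27, and of 27 between responses 27, 24, 21 and 17. Of 315 list scores under other scalings 278 stayed on their side of the threshold, 28 no longer passed, 7 now passed and 2 changed sign where a value passed. A change of sign where neither value passed is counted among the 278. The slide of an array is not given, so a block on slide was not run. Moderated variances with a trend and robust moved no count by over 1.5 times. Signals near background limit what can be seen of dim genes. The cause of a change was not tested. A fit with fewer arrays need not call fewer genes, as het at 1 h against 0 h had 2139 calls over all arrays and up to 2262 without 1 array.

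In the order PM against het, KO against het and PM against KO, the calls were 6, 4 and 5 at 0 h, 16, 4 and 1 at 1 h, 215, 663 and 213 at 4 h, and 10, 151 and 28 for the responses at 4 h. With the replicate number as a block they were 25, 14 and 25, then 36, 20 and 42, then 361, 1153 and 441, then 46, 351 and 65, with 1 for KO against het in the responses at 1 h, and each gene called before was among them. The block is a pairing only where all pairs correlate, which fails for PM against het and KO against het at 0 h, for PM against KO at 4 h and for the 4 h responses of PM and of KO, and 30 of 36 arrays correlate best with their own number. With the number as a random effect they were 24, 12 and 23, then 33, 12 and 30, then 363, 1104 and 412, then 45, 349 and 69. Array weights gave 36, 8 and 45, then 38, 13 and 12, then 380 and 1182 for the first 2 at 4 h, then 51, 386 and 47. With only the arrays compared they were 0, 0 and 0, then 0, 1 and 0, then 67, 391 and 56, then 0 for PM against het and 12 for PM against KO, and 1042 for PM at 1 h against 0 h. Replicates 1 to 3 gave 2 for KO against het and 1 for PM against KO at 0 h, 6 for PM against het and 2 for PM against KO at 1 h, 107 for PM against het at 4 h, and 75 and 8 for the responses of KO against het and PM against KO at 4 h.

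Median scaling gave 594, 600 and 787 for het, PM and KO at 1 h against 0 h and 2699, 2273 and 1746 at 4 h. Between genotypes it gave 2 for KO against het and 2 for PM against KO at 0 h, 2 for PM against het at 1 h, 31, 73 and 32 at 4 h, and 11 and 3 for the responses of KO against het and PM against KO at 4 h. With it the ribosome biogenesis score at 1 h reversed, to -0.0685 in PM and -0.0575 in KO, and the share of the het response kept was 106% for the PM falls at 1 h, 117.8% for the KO falls at 1 h and 77.4% for the KO rises at 4 h. Over genes with a change of at least 2 (log2) KO kept 85.3% of the rise and 83.6% of the fall at 4 h. The authors' table gave 12 for PM against het and 9 for PM against KO at 0 h, 4 for PM against KO at 1 h, 2 for PM against het and 2 for PM against KO in the responses at 1 h, and 24 for PM against het in those at 4 h. No background correction gave 15 for PM against het and 2 for KO against het at 0 h, 3 for PM against KO at 1 h and 20 for the response of PM against het at 4 h. No filter gave 3 for PM against het and 3 for PM against KO at 0 h and 2 for PM against KO at 1 h. The stricter filter gave 3 for PM against KO at 0 h and 3 for the response of PM against het at 4 h. The mean of the probes, and every probe on its own, gave 2 each for PM against KO at 1 h.

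Without 1 array at a time the calls ranged, for 1 h and 4 h against 0 h, over 1633 to 2262 and 3956 to 4055 in het, 1397 to 1881 and 3502 to 3722 in PM, and 1700 to 2188 and 3201 to 3364 in KO. Between genotypes they ranged over 0 to 7, 1 to 5 and 1 to 8 at 0 h, 2 to 17, 2 to 9 and 0 to 4 at 1 h, and 128 to 249, 463 to 692 and 114 to 203 at 4 h, and for the responses at 4 h over 6 to 20, 90 to 183 and 9 to 27. The responses at 1 h had 0 calls in each such fit, with 56, 44 and 68 genes at an unadjusted limma p under 0.05 over all arrays. The share kept ranged over 84.6 to 98.0% (PM rises), 90.7 to 104% (KO rises), 80.5 to 93.8% (PM falls) and 94.6 to 111% (KO falls) at 1 h, and over 87.4 to 91.8%, 80.1 to 82.8%, 82.6 to 88.5% and 78.5 to 81.5% at 4 h. The B cell markers of PM against het at 0 h ranged from -0.47 without het replicate 2 to 0.0169, the other sign, without het replicate 3.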

Other observations

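The genes named in this part by their mean over the 3 times were singled out after their values were seen, and the other tests of this part were planned. Foxp3 was lower in KO than in het at every time, with differences of -0.97, -0.74 and -1.37 (log2 at 0, 1 and 4 h), a mean of -1.02 (limma adjusted p = 4.67e-05 over the mean of the 3 times). In all 196 genes passed over the mean of the times in KO. Others of these were Erdr1 (-1.89), Ppic (-1.40, limma adjusted p = 3.57e-10) and the cytotoxic cell gene Ctsw (-0.96). The B cell genes Mzb1 (-0.95) and Fcmr (-0.91) were lower too. So was Myc (-1.17, limma adjusted p = 0.0440), by -0.24, -1.63 and -1.63 at 0, 1 and 4 h. On the higher side were, among others, Dennd2d (0.70), Elovl6 (0.59) and Whrn (0.58). In PM the mean also passed for Erdr1 (-1.72), Ppic (-0.90), Fcmr (-0.81) and Golm1 (-0.66, and -0.76 in KO). PM and KO are set against the same het arrays, which alone favours shared genes. Of the 141 PM genes with no response difference at an unadjusted limma p under 0.05, most were higher than in het. Among these were Oasl2 (1.46), Gvin1 (1.39), Ifit3 (1.37), Gbp2 (1.34), Gzmk (0.74) and Cxcr3 (0.72).

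In 5 lists camera called no comparison among the 21. Glycolysis genes moved by 0.29 in het at 4 h (adjusted p = 0.430), and the lowest adjusted p of the list was 0.155. CD4 markers stood at -0.23 in PM against het at 4 h (adjusted p = 0.0690). Erythroid and platelet markers moved by -0.81 in het at 4 h (adjusted p = 0.744) and gamma-delta and innate-like markers by -0.40 (adjusted p = 0.698). The means of housekeeping genes lay between -0.07 and 0.08 in all 21 comparisons.

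All 35 splits of the 8 arrays of a comparison were fitted, and 100 drawn ones for the differences of responses, the real split included. For stimulated against resting cells the real split called most in each case, 1 of 35 being as large. That is the smallest share 35 splits can give, and it was not adjusted over the comparisons. Chance is thus argued against in each comparison but not excluded. The real counts and the highest of the other splits were 2139 and 628 for het at 1 h, 4186 and 1246 for het at 4 h, 1777 and 936 for PM at 1 h, 3875 and 1307 for PM at 4 h, 2133 and 436 for KO at 1 h and 3502 and 645 for KO at 4 h. Between genotypes at 4 h the real split also called most, with the same limit (215 and 60 for PM and het, 663 and 126 for KO and het, 213 and 15 for PM and KO). At 0 h too 1 of 35 splits called as many (6 and 1, 4 and 1, 5 and 2), which argues against chance for these few calls in this fit only. There fits with only the arrays compared gave 0, 0 and 0 calls, and those without 1 array as few as 0, 1 and 1. Genes without overlap numbered 173, 122 and 174, where chance gives 217 if the 8 arrays are interchangeable. Differences between replicates can lower that number, so a count below it does not show the lack of a difference. At 1 h 2, 3 and 7 of 35 splits called as many (16 and 27, 4 and 12, 1 and 18), so over all splits chance cannot be excluded. The replicate numbers pair these arrays, and the highest other splits parted 0, 2 and 0 of the 4 pairs, so they also measure differences between replicates. Among the 8 splits that part every pair the real one alone called genes, the highest other being 0, but 8 are too few for a share under 0.05. With the replicate number as a block the counts at 1 h were 36, 20 and 42. For the responses at 4 h 4, 3 and 4 of 100 splits called as many (10 and 46, 151 and 265, 28 and 303), under the 5 set beforehand but too near it to exclude chance firmly. At 1 h 100 of 100 did (0 and 85, 0 and 3, 0 and 778). The real counts there were 0, so this was fixed by construction and says nothing about chance. A split that calls many times the real count, as the 778, 303 or 18 here, points to a structure of the samples. In the 10 comparisons where the replicate numbers pair the arrays, the real split called the most of the 8 that part every pair, and the highest other splits parted 2 or 0 of the 4 pairs.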
